A study of Mus musculus with 4 samples.

How the data were processed

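RNA from whole eyes of 6-week-old mice lacking both Abca4 and Rdh8 was sequenced at 4 conditions: without light exposure, and 3 h, 24 h and 7 days after light exposure. The tissue label reads whole eye, whereas the extraction protocol in the labels speaks of retinas being removed before freezing. The lens transcripts in every sample show that lens RNA was included. Per the labels, RNA was extracted with a spin-column kit and libraries were made with a TruSeq RNA kit, with no statement on strand, and each condition is described as eyes of 3 mice. The series design speaks of triplicates, but the deposited table holds 1 value per gene and condition. Whether that value is 1 pooled library or a mean over 3 libraries is not given in the sources used here. The strength and length of the light exposure, the time of day of collection and the sex of the mice are not given there either.

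The deposited values are FPKM, that is, mapped fragments scaled to transcript length and to library size. Per the submitters' processing notes, bcl2fastq 1.8.3, TopHat2 (given as version 2) and Cuffdiff 2.2.1 were used with the mm9 genome build, and the series design adds Cufflinks. The gene annotation, the library scaling within Cuffdiff and the handling of fragments that map to several places are not given in the sources used here. FPKM values add up to different totals, from 626973 in the control to 680305 at 3 h, so a change in a few very abundant transcripts can move the value of every other gene. The reference tables at hand belong to the GRCm38 assembly, which is not the build of the deposited values, so no coordinates are given. Those tables served only for gene classes, and 22324 of the 22558 listed symbols (99.0%) matched. A further 26 listed names are plain numbers.

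Read counts were not used here. An approximate depth was read from genes of the olfactory receptor family that were above 0 in a single sample, where the smallest values should stand for 1 fragment. Their median was 0.0448 FPKM in the control, 0.0467 at 3 h, 0.0350 at 24 h and 0.0255 at 7 days, from 16, 14, 17 and 20 genes. On that scale a gene of similar length at 5 FPKM rests on about 112, 107, 143 and 196 fragments, with a counting error of 9.5%, 9.7%, 8.4% and 7.1%. At 1 FPKM the counting error is 21.2%, 21.6%, 18.7% and 16.0%. These errors cover counting only, and not the spread between animals. A second reading, from the commonest ratio of low values shared by 2 samples, put the depth at 24 h at 1.29 times and at 7 days at 1.87 times that of the control.

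Changes were computed as log2 of (FPKM + 1) in one sample over (FPKM + 1) in the other, a scale that understates the change of genes with low values. Fold changes printed with a gene are plain ratios of FPKM. Genes with a mean FPKM of at least 1 over the 4 samples were kept (14194 genes). With 1 value per condition there is no replicate spread, so no test was run and no p-value is given. A gene was counted as higher or lower at an absolute log2 change of at least 1. A gene listed at 0 in a sample is reported as listed at 0, without a fold change. The groups were the 4 labelled conditions. Each light sample was compared with the control, the 24 h sample with the 3 h sample, and the 7-day sample with the 24 h sample.

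The genes named were the 12 with the largest increase and the 12 with the largest decrease against the control among those past the threshold with a mean FPKM of at least 5. Unnamed gene models and most small RNA genes were passed over, as were further genes after the 4th of one list or symbol family. Abca4 and Rdh8 were also to be given in every sample, and any member of a gene list could be named within the account of that list. The values of a few genes that these rules name are not reported here. The 26 gene lists, for cell types of the eye, stress and immune pathways, the circadian clock and tissues that can be left on or in an eye, held 551 entries, of which 545 were found. For each list the median log2 change over the members that passed the filter was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and its percentile describes these samples only. The genes of a list tend to vary together whatever the cause, and 51 of the 78 list comparisons with the control lay outside the central 95% of random lists, so no statement rests on a percentile alone. The rules above, the lists and most alternatives were chosen before the data were examined.

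The alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, rescaling by the median ratio, rescaling to the same sum without the lens, skeletal muscle, erythroid and surface epithelium lists, and leaving out genes that belong to more than 1 list. Restriction to protein-coding genes, removal of genes listed at 0 in any sample and a rescaling that also leaves out small RNA genes were added after seeing the data. Additional lists of collagen and elastic fibre, resident fibroblast, glucocorticoid-responsive and adipocyte genes were also drawn up after the main results were seen. Bootstrap intervals are 95% intervals from 10000 draws over genes, which are not independent replicates. The counting and list steps were tested on simulated data for the comparison of 24 h with control, in which 95.3% of 192 genes changed 4-fold were recovered among 14183 genes, 0 unchanged genes were counted, a rod list set to -0.6 gave a median of -0.59, and 6% of unchanged lists fell outside the central band. The simulation assumed a spread between samples of 0.1 on the log2 scale, which the deposited table cannot check. It gave every gene the same FPKM per fragment and let genes vary independently. Genes of other lengths, small RNA genes among them, and lists whose genes vary together were not modelled. The simulated rates therefore may not hold for the deposited values. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.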

Results

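Whole-eye transcriptomes were measured in mice lacking Abca4, the photoreceptor flippase that clears retinaldehyde from disc membranes, and Rdh8, a photoreceptor retinol dehydrogenase. Such mice clear all-trans-retinal slowly and are used as a model of light-induced retinal degeneration. The series compared eyes of 6-week-old mice without light exposure with eyes taken 3 h, 24 h and 7 days after it, asking which transcripts change after light. One FPKM value per gene was deposited for each condition, labelled as eyes of 3 mice, so none of the differences below has a replicate check. Abca4 was at 56.3 FPKM in the control, 40.6 at 3 h, 34.3 at 24 h and 37.4 at 7 days, and Rdh8 was at 10.5, 14.2, 11.9 and 11.02 FPKM. These values cover whole genes rather than the deleted parts, and all samples carry the same genotype, so they check no label. Lens genes took 24.4% of all FPKM in the control, 20.9% at 3 h, 24.9% at 24 h and 23.9% at 7 days, and small RNA genes took 12.7%, 18.1%, 13.7% and 15.6%.

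Most transcripts differed little between samples. Among 10168 protein-coding genes with a mean FPKM of at least 5, 77.1% lay within 0.2 log2 units of the control at 3 h, 75.9% at 24 h and 83.9% at 7 days. At 3 h, 78 genes were at least 1 log2 unit higher than in the control and 34 lower, at 24 h 106 were higher and 51 lower, and at 7 days 58 were higher and 27 lower. Many of these were small RNA genes, often listed at 0 in a sample. The protein-coding genes among them numbered 37 higher and 15 lower at 3 h, 60 and 29 at 24 h, and 24 and 7 at 7 days.

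**Figure D1:**
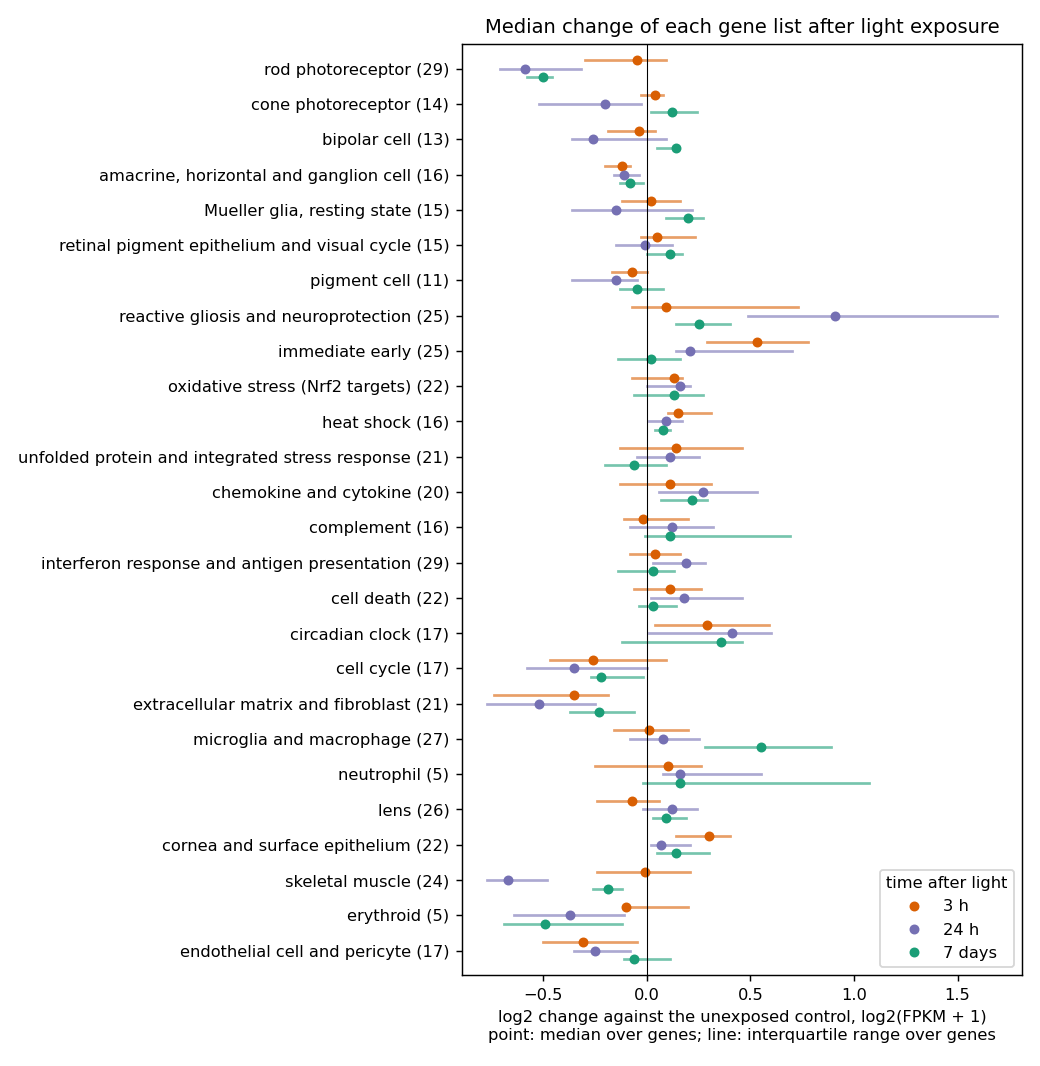
Median log2 change of each gene list against the unexposed control (horizontal axis, log2 of FPKM + 1), for 3 h, 24 h and 7 days after light exposure. Points are medians over the genes of a list, lines the interquartile range over genes (not an error between animals), and the number of genes is in brackets. The gliosis list lay highest at 24 h (0.91), the microglia and macrophage list at 7 days (0.55) and the immediate early list at 3 h (0.53), while the rod list was at -0.59 at 24 h and -0.50 at 7 days.

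The comparison of 3 h with the control addressed the early response. The genes with the largest increases included Cebpd, Angptl7 and Tsc22d3, and those with the largest decreases included the elastin gene and 3 fibrillar collagen genes. Tsc22d3, a glucocorticoid-induced leucine zipper protein, was 4.23-fold higher (29.0 to 122.5 FPKM), and Fkbp5, a co-chaperone of the glucocorticoid receptor, was 3.15-fold higher. Cebpd, an acute-phase transcription factor, was 5.75-fold higher (4.58 to 26.3 FPKM). Angptl7, a secreted protein of the anterior eye, was 4.66-fold higher (60.9 to 283.9 FPKM). The immediate early list had a median log2 change of 0.53, with 5 of 25 genes past the threshold, 23 of 25 above 0 and none past it downwards. Egr1 was 3.90-fold and Fos 3.31-fold higher, and Jun went from 21.9 to 51.0 FPKM. Atf3 went from 2.59 to 7.70 FPKM.

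Also higher at 3 h were the metabolic genes Fmo1 (3.71-fold), Sult1a1 (3.22-fold) and Ip6k2 (3.07-fold). The adipocyte fatty acid binding protein Fabp4 was 3.07-fold higher and the adipsin gene Cfd 2.93-fold higher. In the gliosis and neuroprotection list, 6 of 25 genes were higher at 3 h, although its median was only 0.09. The median turned to -0.05 after rescaling without lens, muscle, erythroid and surface epithelium genes. It stayed above 0 when small RNA genes were left out of that sum too. The 6 included Cebpd, Lif (0.409 to 2.84 FPKM), a cytokine released by stressed Müller glia, and the metallothioneins Mt1 (325 to 794 FPKM) and Mt2 (161.1 to 375 FPKM). Gfap, the intermediate filament of reactive glia, was not among them (18.3 and 15.5 FPKM). Surface epithelium genes had a median of 0.30, with Krt14 going from 32.3 to 68.6 FPKM and Krt16 from 0.442 to 1.97 FPKM. The circadian clock list had a median of 0.29, and Per2 went from 2.40 to 7.49 FPKM.

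Among the genes lower at 3 h, Eln, which encodes elastin, was at 0.31 of its control level, and the fibrillar collagen genes Col3a1, Col1a1 and Col5a1 were at 0.46, 0.48 and 0.48. The extracellular matrix list had a median of -0.35, with 3 of 21 genes past the threshold and 19 of 21 below 0. The proteoglycan genes Dcn (768.5 and 759.7 FPKM) and Lum (124.7 and 126.1 FPKM) of the same list differed little. Endothelial and pericyte genes had a median of -0.31, with 15 of 17 below 0 and none past the threshold, and Cldn5, a tight junction gene of vessels, went from 27.6 to 13.9 FPKM. Cell cycle genes had a median of -0.26, which was 0.09 among the 3 of 17 with a mean FPKM of at least 5. The bicarbonate transporter-like gene Slc4a11 was at 0.26 of its control level, and the neuropeptide genes Npvf and Npy were at 0.34 and 0.44. Cd248 was at 0.44, Chst5 at 0.45 and Efhd1 at 0.44.

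Rod genes at 3 h had a median of -0.05, with 12 of 29 above 0 and none past the threshold. The medians were 0.04 for cones, -0.04 for bipolar cells, -0.12 for amacrine, horizontal and ganglion cells, 0.02 for resting Müller glia, 0.05 for the pigment epithelium and visual cycle and -0.07 for pigment cells. They were 0.01 for microglia and macrophages, -0.02 for complement, 0.04 for interferon and antigen presentation, 0.10 for neutrophils, -0.07 for lens, -0.01 for skeletal muscle and -0.10 for erythroid cells. Heat shock genes (0.15), Nrf2 targets (0.13), unfolded protein response genes (0.14), chemokines and cytokines (0.11) and cell death genes (0.11) lay slightly above 0. Each of these 5 medians fell below 0 under the rescaling without lens, muscle, erythroid and surface epithelium genes. That rescaling shifted the 3 h sample against the control by 0.18 log2 units and gave 61 higher and 50 lower genes in place of 78 and 34. Small RNA genes feed its sum. Leaving them out too gave a shift of 0.07 and reversed none of these medians.

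Hist1h4j was listed at 0 in the control and at 15.3, 8.95 and 5.08 FPKM at 3 h, 24 h and 7 days. It belongs to a family of near-identical histone genes, so its values are uncertain. The same holds for Hist1h4k. Amd1 was at 9.12 FPKM in the control, 0.0225 at 3 h, 13.4 at 24 h and 1.58 at 7 days. Its near-identical copy Amd2 was at 56.9, 69.5, 51.3 and 59.3 FPKM, and fragments may have been divided differently between the copies, so Amd1 is uncertain too.

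At 24 h the leading change was in genes of reactive glia. The gliosis and neuroprotection list had a median log2 change of 0.91, with 12 of 25 genes higher, none lower and 23 above 0. Serpina3n, a protease inhibitor of reactive astrocytes and Müller glia, was 6.91-fold higher (28.5 to 196.9 FPKM), and Gfap was 5.07-fold higher (18.3 to 93.0 FPKM). Lcn2, an acute-phase lipocalin, was 7.93-fold higher from a low level (1.76 to 14.0 FPKM). Edn2, an endothelin made by injured photoreceptors, went from 0.761 to 10.01 FPKM, and Socs3, a feedback inhibitor of cytokine signalling, from 4.13 to 22.8 FPKM. Stat3 went from 20.4 to 54.2 FPKM and Osmr, the oncostatin M receptor, from 6.33 to 22.7 FPKM. Cebpd was 6.78-fold higher.

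Other cell types of the retina differed in a mixed way at 24 h. Rod genes had a median of -0.59, with 26 of 29 below 0 and 2 past the threshold. Nr2e3, a rod transcription factor, was at 0.43 of its control level, and Pdc, phosducin, went from 1046 to 516 FPKM. Nrl went from 588 to 304 FPKM. Aipl1, Rbp3 and Sag lay above 0 (log2 changes of 0.24, 0.19 and 0.15). Cone genes had a median of -0.20, with Opn1sw (130.3 to 60.1 FPKM) past the threshold downwards and Gnb3 (79.5 to 193 FPKM) upwards. The resting Müller glia list had a median of -0.15. Within it Crym, a thyroid hormone binding protein, was 6.40-fold higher, while the glutamine synthetase gene Glul went from 769 to 395 FPKM. Medians were -0.26 for bipolar cells, -0.11 for amacrine, horizontal and ganglion cells, -0.01 for the pigment epithelium and visual cycle and -0.15 for pigment cells. Nxnl1, a photoreceptor thioredoxin-like gene, was at 0.45 of control.

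Immediate early genes at 24 h had a median of 0.21, with Atf3 5.95-fold and Junb 3.10-fold higher. The interferon and antigen presentation list had a median of 0.19, with 2 of 29 genes past the threshold, among them Irf9 (13.6 to 28.3 FPKM). Chemokines and cytokines had a median of 0.27, with Ccl2 (0.440 to 2.35 FPKM) and Ccl12 (2.29 to 7.29 FPKM) past it. The cell death list had a median of 0.18, with Gadd45b going from 10.1 to 29.3 FPKM, and the complement list 0.12, with Cfi going from 0.398 to 2.86 FPKM. Medians were 0.16 for Nrf2 targets, 0.09 for heat shock, 0.11 for the unfolded protein response, 0.41 for the clock, -0.35 for the cell cycle (0.20 among the 3 of 17 with a mean FPKM of at least 5), 0.08 for microglia and macrophages and 0.16 for neutrophils. Glycam1 was 6.89-fold, Lrrc2 4.14-fold, Klhl29 3.87-fold and Sec22c 3.71-fold higher.

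The matrix list remained low at 24 h, with a median of -0.52 and 4 of 21 genes past the threshold. Eln was at 0.26 of control, Col3a1 at 0.37 and the fibrillin gene Fbn1 at 0.40. Endothelial and pericyte genes had a median of -0.25 and erythroid genes -0.37. Skeletal muscle genes had a median of -0.67, with 23 of 24 below 0 and 1, Myh2, past the threshold. Myh2 was at 0.42 and Myh3 at 0.45 of control, so the 24 h sample held a smaller share of muscle RNA. Lens genes (0.12) and surface epithelium genes (0.07) lay near 0. Npvf was at 0.27, Spc25 at 0.32, Ccdc24 at 0.36, Slc4a11 at 0.37 and Pdk4, a kinase that restrains pyruvate use, at 0.31 of control.

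**Figure D2:**
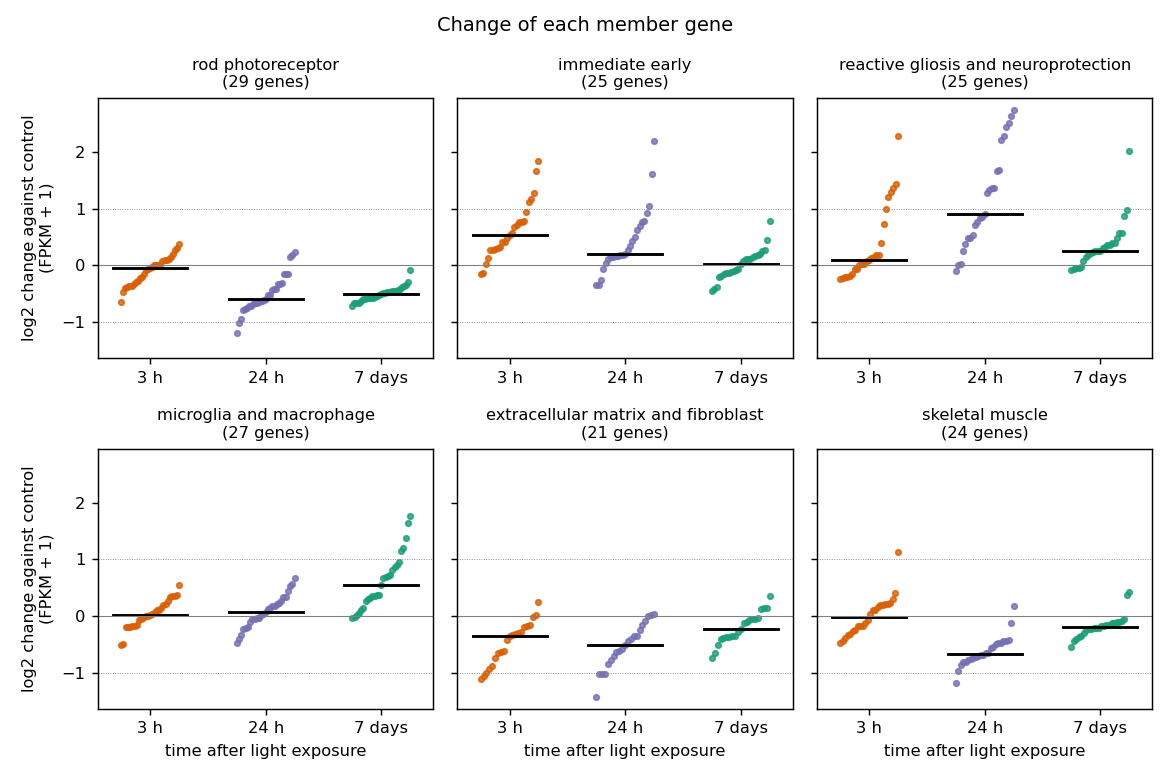
Log2 change against the control (vertical axis, log2 of FPKM + 1) of each gene of 6 lists at 3 h, 24 h and 7 days. Each point is a gene, sorted within a time, the bar is the median, and dotted lines mark the threshold of 1. All 29 rod genes lay below 0 at 7 days, and 12 of 25 gliosis genes lay above the upper line at 24 h.

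At 7 days the genes of microglia and macrophages led the change. Their list had a median of 0.55, with 5 of 27 genes higher, none lower and 25 above 0. Tyrobp, a signalling adaptor of myeloid receptors, was 3.29-fold higher (13.6 to 44.9 FPKM), and its partner receptor Trem2 went from 2.14 to 9.62 FPKM. The lysosomal gene Cd68 was 2.96-fold, the perforin-like gene Mpeg1 2.66-fold and the Fc receptor chain Fcer1g 2.37-fold higher. The complement genes C1qa, C1qb and C1qc were 2.43-, 2.48- and 2.44-fold higher, while the complement list as a whole had a median of 0.11. Some myeloid genes differed less, among them Tmem119 (9.87 and 10.7 FPKM) and Ccr2 (2.19 and 2.24 FPKM). In the neutrophil list (median 0.16, 5 genes), S100a8 went from 1.14 to 3.49 and S100a9 from 1.22 to 4.80 FPKM.

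The 7-day sample differed from the others in sex-linked transcripts. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were at 6.59, 6.80, 3.68 and 1.38 FPKM, against at most 0.0137 FPKM in any other sample. Xist, which is expressed from the inactive X chromosome, was at 37.1 FPKM, 72% of the mean of the other samples. The 7-day sample thus held male tissue and the other samples next to none, so sex differs along with time in each comparison of the 7-day sample, that of microglial genes included. Of the 58 genes higher at 7 days, 2 were Y-linked.

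Rod genes were still low at 7 days, with a median of -0.50 and all 29 below 0, though none past the threshold. Nrl was at 380 FPKM, against 588 in the control. Other retinal lists lay above or near 0, at 0.12 for cones, 0.14 for bipolar cells, 0.20 for resting Müller glia, 0.11 for the pigment epithelium and visual cycle, -0.05 for pigment cells and -0.08 for amacrine, horizontal and ganglion cells. The gliosis list had a median of 0.25, with Edn2 (6.18 FPKM) past the threshold and Gfap at 36.8 FPKM. The clock list had a median of 0.36, and the clock output gene Dbp was 2.03-fold higher. The matrix list had a median of -0.23, and Eln was at 0.44 of control. Medians were 0.02 for immediate early genes, 0.13 for Nrf2 targets, 0.08 for heat shock, -0.06 for the unfolded protein response, 0.22 for chemokines and cytokines, 0.03 for interferon and antigen presentation, 0.03 for cell death and -0.22 for the cell cycle (-0.02 among the 3 of 17 with a mean FPKM of at least 5). They were 0.09 for lens, 0.14 for surface epithelium, -0.19 for skeletal muscle, -0.49 for erythroid cells and -0.06 for endothelial cells and pericytes.

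Further genes higher at 7 days were Hist1h4k (2.62-fold), the small RNA gene Rnu73b (2.27-fold) and Lars2 (2.01-fold, 2740 to 5510 FPKM). Lower were the small RNA gene Rnu11 at 0.31 and the pseudogene Pisd-ps1 at 0.42 of control.

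**Figure D3:**
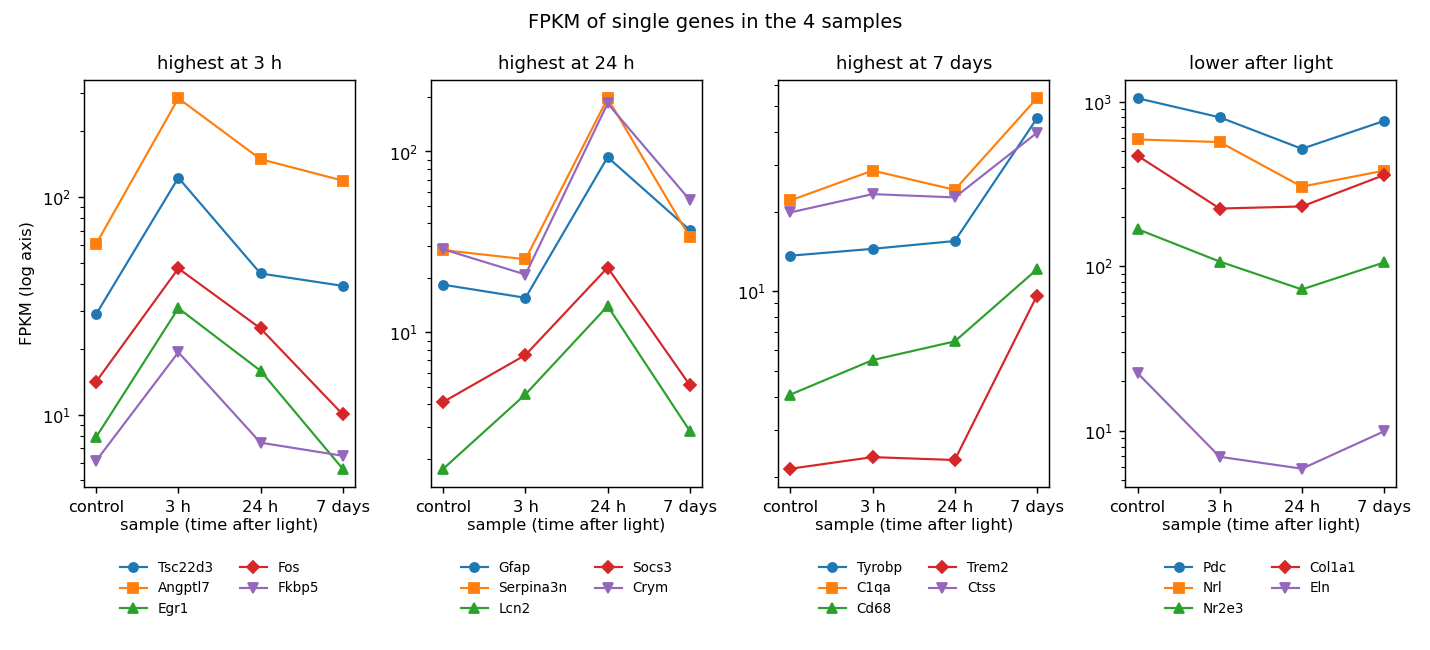
FPKM (vertical axes, log scale, different in each panel) of single genes in the control and 3 h, 24 h and 7 days after light exposure; each point is 1 deposited value and lines only join samples. Gfap was highest at 24 h (93.0 FPKM), Tyrobp at 7 days (44.9 FPKM) and Tsc22d3 at 3 h (122.5 FPKM).

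Successive times were also compared directly, which leaves out the control that the comparisons above share. They share the 24 h value instead, so a deviation of that sample would move them in opposite directions. From 3 h to 24 h, 73 genes were higher and 62 lower, or 89 and 49 after the rescaling without lens, muscle, erythroid and surface epithelium genes. The gliosis list had a median of 0.69 with 10 of 25 genes higher, the rod list -0.43 and skeletal muscle -0.67 with all 24 genes below 0. From 24 h to 7 days, 42 genes were higher and 73 lower. The gliosis list then had a median of -0.62 with 10 of 25 genes lower, the microglia and macrophage list 0.55 with 24 of 27 above 0, and the immediate early list -0.31. The rod list was at 0.05, the cone list at 0.36, the matrix list at 0.29 and skeletal muscle at 0.45 with all 24 genes above 0.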

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

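The tests of less retina, of the rod spread against protein-coding genes and of connective tissue were chosen after the results were seen. The bounds for the spread of rod genes against 3 h and for the medians of the adipocyte and glucocorticoid-responsive lists were written before those figures were computed, though the rod genes, Per1 and Ddit4 were already in the main lists. The connective tissue test was run in turn on 12 fibroblast genes, on 7 of these and on the matrix list, was first read as deciding against that explanation, and is now taken as void. Setting aside the bound for adipocyte genes was also decided after their values were seen.

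Several lists moved in opposite directions at 24 h and 7 days against the same control, and none of these differences was tested. The median log2 change was -0.20 at 24 h and 0.12 at 7 days for cone genes, -0.26 and 0.14 for bipolar cell genes, and -0.15 and 0.20 for resting Müller glia genes. The unnamed gene model 1700027L20Rik had a log2 change of 3.62 at 24 h and -1.60 at 7 days, and Gm4792 had 1.12 at 3 h, -1.78 at 24 h and -1.93 at 7 days. These 2 gene models stood outside the rule for naming and are given because their changes had opposite signs.

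Rod transcripts were lower at 24 h and 7 days, with 26 and 29 of 29 genes below 0, 2 and none of them past the threshold. A smaller share of retina in the sample would lower the other retinal neurons alike, but rod genes lay below those of bipolar, amacrine, horizontal and ganglion cells by a log2 difference of -0.46 at 24 h (95% bootstrap interval over 29 and 29 genes, -0.59 to -0.24) and of -0.50 at 7 days (-0.59 to -0.40). Those other neurons had a median of -0.13 at 24 h and -0.01 at 7 days, so less retina as a part of the decrease at 24 h stays open. A loss of rods that otherwise keep their transcripts would lower all rod genes by about the same factor. At 7 days the SD of the rod genes was 0.52 times that at 3 h. It was 1.02 times the robust SD of protein-coding genes with a mean FPKM of at least 5. Such a loss would give ratios like these, but so would an even fall in the level per rod, so they do not separate these causes. At 24 h the first ratio was 1.36. Beforehand, such a loss was to need an SD no larger than at 3 h, and a ratio above 1.5 was to speak against it. The ratio of 1.36 lay between these bounds and decided nothing. The second yardstick, added after that value was seen, gave 2.24. It gave 1.63 at 3 h too, where the rod median was near 0, so it decides nothing. Fewer rods and a lower level per rod cannot be told apart at 24 h or at 7 days. Light, sex at 7 days and any difference between animals stay open for both times, since each condition has 1 value.

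Collagen and elastic fibre genes had medians of -0.75 at 3 h and -0.85 at 24 h, with 4 and 6 of 13 past the threshold and all 13 below 0. Less connective tissue in the light samples would lower other fibroblast and matrix transcripts by as much, and the 13 genes lay below the 12 other genes of the matrix list by a log2 difference of -0.52 at 3 h (interval -0.83 to -0.36) and of -0.55 at 24 h (-0.95 to -0.20), below 12 resident fibroblast genes by -0.61 (-0.88 to -0.44) and -0.67 (-1.04 to -0.42), and below the 7 of these in no fixed list and not named by -0.62 (-0.90 to -0.18) and -0.67 (-1.01 to 0.02). The 13 genes were listed after the results were seen and include some of the largest decreases, and the other matrix genes are what that choice left over, so the way the genes were chosen may account for much of these gaps and they decide nothing. Less connective tissue and lower collagen transcripts per cell therefore cannot be told apart at either time. The control had the highest value for 16 of the 21 genes of the matrix list, so a control sample with unusually high collagen stays as open as an effect of light, and neither was tested.

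Glucocorticoid-inducible genes, among them Tsc22d3 and Fkbp5, were higher at 3 h, and 11 other responsive genes all lay above 0, 1 of them past the threshold, with a median of 0.62 at percentile 100 of random lists (Per1 and Ddit4 of these are also in the clock and unfolded protein lists). Orbital fat left on the eyes is another possible source: 9 adipocyte genes had a median of 0.28 (interval 0.08 to 0.88), under the bound of 1 written beforehand, but 6 of the 9 were at 5 FPKM or more in the control, Car3 at 74.7 FPKM, so that bound was unsuited, since such levels would hide a small share of fat. Of the 3 others, Cidec went from 0.520 to 3.31 FPKM and Adipoq from 1.18 to 3.02 FPKM. Retn differed little (1.25 to 1.39 FPKM), and only Cidec passed the threshold. The adipocyte genes Plin1 (0.486 to 1.55 FPKM) and Lep (0.0305 to 0.157 FPKM), left out by the filter, were also higher at 3 h, though at low values. Fat as a part or the whole of the source, light, handling or restraint, and the time of day may each contribute, and the design does not separate them.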

How the results depend on the processing

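No paired analysis was possible because the table holds 1 value per condition, and the planned omission of each replicate was not run for the same reason. The counts kept within 1.5 times their main value under the planned rescalings and without a filter. With a pseudocount of 0.1, lower genes numbered 54 at 3 h, 92 at 24 h and 99 at 24 h against 3 h, and 73 were higher at 7 days against 24 h. With a mean FPKM of at least 5, 38 genes were higher at 7 days.

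The remaining settings with moved counts were chosen after seeing the data. Protein-coding genes alone gave 37 higher and 15 lower at 3 h, 60 and 29 at 24 h, 24 and 7 at 7 days, 45 and 32 at 24 h against 3 h, and 15 and 44 at 7 days against 24 h. Without genes listed at 0 in any sample there were 17 lower at 3 h, 32 higher and 12 lower at 7 days, 48 higher and 40 lower at 24 h against 3 h, and 18 higher at 7 days against 24 h. The first leaves out small RNA genes by construction, and 71 of the 74 genes that the second leaves out are small RNA genes.

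With a mean FPKM of at least 5 the median reversed to -0.02 for chemokines at 3 h (10 of 20 genes left), and to 0.09 at 3 h and 0.20 at 24 h for the cell cycle, of which only 3 of 17 genes are left, so that each of these medians is the value of 1 gene. Rescaling without lens, muscle, erythroid and surface epithelium genes reversed 6 medians at 3 h, to -0.05 for gliosis, -0.05 for Nrf2 targets, -0.02 for heat shock, -0.04 for the unfolded protein response, -0.01 for chemokines and -0.04 for cell death. It moved 3 h against control by 0.18 log2 units, and the small RNA gene Scarna2, at 17540 FPKM in the control and 43700 at 3 h, feeds that sum. Leaving out small RNA genes too gave 0.07 and reversed none of the 78 medians. All 64 named gene changes kept their direction and threshold side with a pseudocount of 0.1 and under the median ratio, and the naming rule chose 60 and 64 of them again. Depth limits genes near 1 FPKM most, with counting errors of 16.0% to 21.6%, and no setting can replace the missing replicates.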

Other observations

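In each light sample 1 of the 17 clock genes was past the threshold against the control, Per2 at 3 h and Dbp at 24 h and 7 days. Per2 was at 2.40 FPKM in the control and at 7.49, 5.74 and 4.84 FPKM at 3 h, 24 h and 7 days, Per3 at 10.5, 18.1, 16.3 and 17.1 FPKM, and Tef at 52.2, 84.5, 80.9 and 78.4 FPKM. Dbp was at 40.6, 58.2, 86.3 and 82.5 FPKM. Arntl, which peaks at the opposite phase to Dbp, was at 25.5, 26.0, 18.3 and 16.3 FPKM. The control was lowest for 10 of the 17 clock genes, but also for 16 of 22 surface epithelium and 11 of 16 heat shock genes, and for 0 of 29 rod genes. Genes of a list vary together, so this count is not particular to the clock and was not tested. The times of day of collection are not given in the sources used here.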
